A study of Sus scrofa with 32 samples.

How the data were processed

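The deposited series holds 32 CUT&Tag samples of porcine muscle satellite cells: 24 libraries of H3K4me3, H3K27ac and H3K27me3 and 8 IgG libraries. Per the labels, cells were untreated (WT) or given SGC-CBP30 (CBP), for 48 h in proliferation and for 60 h in differentiation. The dose is given there as 5 with the unit uM/ml, whose meaning is not settled by the sources used here. The 12 groups were 3 marks in 4 conditions (WT and CBP, at 0 h and 60 h) with 2 libraries each. The 8 IgG samples were not analysed here. The labels conflict: the treatment field gives proliferation for the 60 h samples too, and the growth protocol and cell line fields name C3H cells, kept in RPMI, beside the pig organism and satellite cell fields. Time and cell type were taken from the sample titles and the cell type field. Nothing states that replicates are separate cultures.

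The authors deposited one peak list per library, narrow for H3K4me3 and H3K27ac and broad for H3K27me3. Per the labels, Trimmomatic (version not given), MACS2 2.1.0 and the pig build Sscrofa11.1 were used. The aligner, the options, the control library used for calling and the read depth are not given in the sources used here, so the depth per sample and the precision it gives could not be stated. In the files as deposited, the score column holds the display score of MACS2, about 10 times the -log10 q. The ratio column, as deposited, holds the fold enrichment over the local background that MACS2 estimated in that library. The columns of -log10 p and -log10 q, as deposited, hold the peak's significance from MACS2. A further column of the narrow lists, as deposited, holds the offset of the summit in bp. Each was computed within its own library, so only peak positions entered the comparisons of length, regions and genes. Deposited -log10 p values were used to rank peaks within a list, and -log10 q values for a stricter filter. To weigh technical explanations, quantities derived from these columns were set side by side between lists. They were the share of peaks with a -log10 q of at least 5, the background (the Poisson mean whose tail probabilities held the largest share of a list's -log10 p values), and an index of read depth (from that background and the step between the fold values).

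Peaks were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and overlapping peaks of a list were merged for covered length. The build was checked from the share of peaks within 1 kb of an annotated gene end, which was 68.1 to 74.1% for H3K4me3 and 9.02 to 11.1% after all peaks were shifted by 200 kb. The gene table held 19516 protein-coding genes on placed chromosomes and gave no strand. The plan, written before the data were examined, set windows around the transcription start, but without strand both ends of each gene were used instead. The value of a gene was the length under peaks within 5 kb of either end, gene-end states used 1 kb, and a peak was distal when over 2.5 kb from every gene end. Neighbouring genes can share a window. Regions were merged over the 4 libraries of a comparison, an overlap of 1 bp counted as shared, and a region was lost or gained when both libraries of a group had it and neither of the other did. The same count was made for the 2 splits that mix the groups.

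Gene values were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust) on the log2 of base pairs plus 500, for genes with at least 200 bp in at least 2 libraries. Each mark had 1 fit with its 8 libraries and 4 residual degrees of freedom. The 4 contrasts were CBP against WT at 0 h and at 60 h, 60 h against 0 h in WT, and the difference between the CBP effects at the 2 times. Where a group had no listed base the log2 change depends on the added 500 bp, so lengths are given instead. Genes with no listed base in both libraries of at least 1 group numbered 1383 of 12897 in H3K4me3, 6774 of 8967 in H3K27ac and 2703 of 3685 in H3K27me3, and in 3 groups 283, 1398 and 544. Such groups add no spread, and 1, 12 and 3 genes had equal lengths within every group, so their p values rest on the moderated variance. Benjamini-Hochberg adjustment was made within a contrast, with calls at an adjusted p below 0.05. Lists were tested with camera at its preset correlation of 0.01, and again with an estimated one. The 26 lists of cell type, pathway and process genes, fixed before the data were examined, held 922 genes, of which 877 were found in the table. Lists with at least 5 measured genes were tested. Peak numbers, covered length and distal shares were compared by exact permutation tests (two-sided), where 2 against 2 cannot give a p below 0.333. Overlaps of gene sets between marks used Fisher's exact test (scipy 1.17.1), and figures were drawn with matplotlib 3.10.9.

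The rule for named genes, also fixed beforehand, took for each mark and comparison the 10 called genes with the largest increase and the 10 with the largest decrease whose groups do not overlap. It added a fixed panel of 36 genes (34 found) and up to 4 members of a reported list with the smallest p. Fewer are named than the rule takes. The choice among them was made after the results were seen, and genes whose calls depended most on the processing were among those left out. The results of 1 gene of the panel are not reported here.

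The gene test was tested on simulated data with 200 changed genes or none, in 3 forms of noise. With residuals of randomly flipped sign, the form first planned, 14.9 to 25.6% of unchanged genes were called in the altered contrast. In contrasts between unaltered groups up to 2645 of 8967 H3K27ac genes were called. Such calls arise since equal signs in a group leave no spread and a shifted mean. With Gaussian noise of the pooled spread, 0 to 10 unchanged genes were called, and at most 6.96% of calls were false. There, log2 changes of 1 and 2 were recovered for 86.5 and 97% of changed genes in H3K4me3, 39.5 and 73% in H3K27ac, and 0 and 53.5% in H3K27me3. With the spread of each group kept, up to 134 unchanged genes were called in the altered contrast (0 to 3.16% of them) and up to 249 in contrasts between unaltered groups. In the altered contrast with 200 changed genes 34.4 to 57.9% of calls were false, and recovery was 90.5 and 100%, 52.5 and 79.5%, and 40 and 62%. The last 2 forms were added after the first had been run.

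Alternatives were a -log10 q of at least 5, lists of equal length within a mark (the top 14898, 8969 and 1338 peaks by p), windows of 10 kb, gene ends of 2.5 kb, a distal limit of 5 kb, 50% overlap of regions, placed chromosomes only, added lengths of 100 and 2000 bp, no filter, quantile scaling, 4 libraries in the fit, the replicate number as a block, and leaving out each library. After the data were seen, the whole gene span and a window at a single end were added, the end with more H3K4me3 being taken for 12056 genes. Also added then were list tests over the genes with a listed base in at least 1 library at 0 h (12267, 6342 and 3397 genes in H3K4me3, H3K27ac and H3K27me3), for the effect at 0 h and the difference, and the overlap of the time and CBP contrasts with 1 WT library at 60 h in each, over genes that passed the filter in the other 6 libraries. For the overlap of contrasts that share libraries, 20 simulations gave the overlap without any effect.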

Results

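CUT&Tag, which tags the DNA next to an antibody-bound histone, was run in porcine muscle satellite cells, the stem cells of skeletal muscle. The marks were H3K4me3, found at active promoters, H3K27ac, found at active promoters and enhancers, and H3K27me3, found at genes silenced by Polycomb complexes. Each mark had 8 libraries, 2 in each of 4 conditions: untreated (WT) and treated (CBP) cells at 0 h of differentiation and at 60 h. Treated cells received SGC-CBP30, a small molecule that blocks the bromodomains of the acetyltransferases CBP and p300. The peak list of each library was the measurement, and read depth is not given in the sources used here. Peaks per library ranged from 14898 to 17364 for H3K4me3, from 8969 to 23437 for H3K27ac and from 1338 to 19317 for H3K27me3. Nothing in the labels says that replicates were separate cultures, so the spread given is that between libraries. All values with an error are means ± SD over n = 2 libraries, and adjusted p values of genes and gene lists come from limma. Changes are in the length of DNA under peaks within 5 kb of either end of a gene. In simulated data the gene test called at most 10 unchanged genes when all groups had the same spread. When each group kept its own spread it called up to 3.16% of unchanged genes, and 34.4 to 57.9% of its calls were false where 200 genes had been changed. With residuals of randomly flipped sign, the form first planned, it called 14.9 to 25.6% of unchanged genes in the altered contrast. Many calls were of genes with no listed base in both libraries of at least 1 group, which have little spread of their own. At 60 h they made up 3601 of 4467 inhibitor calls in H3K27ac, 574 of 2110 in H3K4me3 and 485 of 531 in H3K27me3, and at 0 h 1993 of 2657, 437 of 5329 and 1917 of 2825. Calls of single genes carry these limits.

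**Figure D1:**
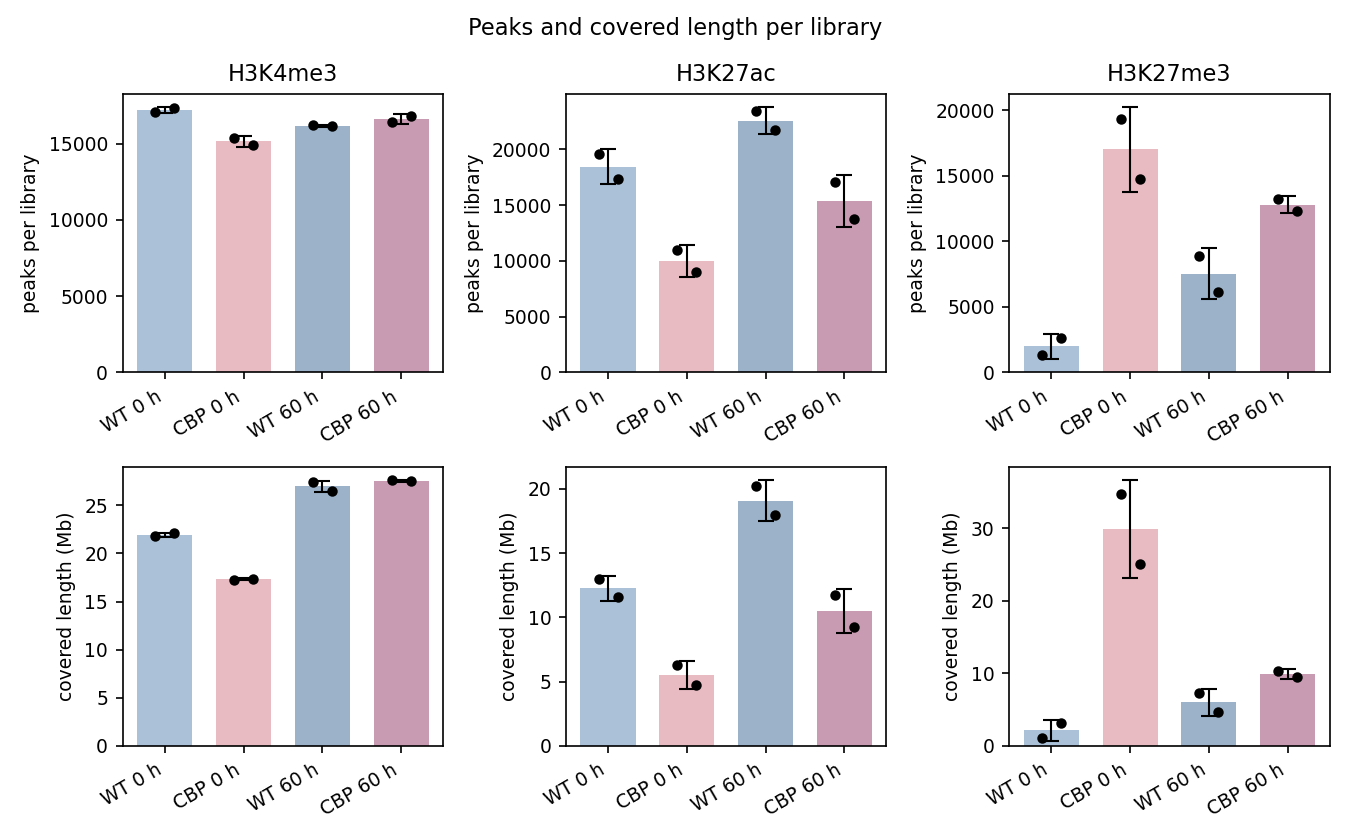
Peaks per library (top) and megabases under peaks (bottom) for the 3 marks in the 4 conditions. Bars are means of 2 libraries, error bars are SD and points are libraries. H3K27ac was lower in CBP than in WT at both times, and H3K27me3 in WT at 0 h was the shortest set of lists, with a mean of 2.11 Mb.

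The first comparison asked how the marks differed between differentiating (60 h) and proliferating (0 h) untreated cells. Of 39 measured contractile and sarcomere genes, 36 rose in H3K4me3 and 0 fell, with a median log2 change of 2.16 against 0.17 in the other genes. Of 25 excitation-contraction coupling genes, which link the nerve signal to calcium release, 21 rose and 0 fell, with a median of 1.91. MYOG, the transcription factor that starts terminal differentiation, had no H3K4me3 or H3K27ac base listed at 0 h, and at 60 h had 3.98 ± 0.0651 kb of H3K4me3 and 4.15 ± 0.204 kb of H3K27ac.

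In H3K4me3, no base was listed at 0 h for ACTC1 and ACTA1, the cardiac and skeletal actins, which at 60 h had 7.51 ± 0.175 kb (adjusted p = 5.74e-07) and 4.53 ± 0.0233 kb (adjusted p = 1.23e-06). The same held for TNNT2, a troponin, with 5.47 ± 0.0735 kb at 60 h, and for TTN, the spring protein titin, with 5.13 ± 0.00566 kb. MYL1, a myosin light chain (gene 397666, Sscrofa11.1 chromosome 15, 113038083 to 113051315), reached 4.29 ± 0.235 kb, and CHRNA1, a subunit of the muscle acetylcholine receptor, reached 4.92 ± 0.136 kb. MYMK, which drives myoblast fusion, reached 4.73 ± 0.187 kb, and MEF2C, a partner of the myogenic factors, reached 3.9 ± 0.582 kb. Their adjusted p values lay between 5.74e-07 for ACTC1 and 3.57e-05 for TTN. MYOD1, a factor that commits cells to muscle, rose from 0.996 ± 0.196 kb to 3.73 ± 0.00424 kb (log2 1.51, adjusted p = 7.26e-05). HEYL, a Notch target, had no base at 0 h and 2.51 ± 0.489 kb at 60 h (adjusted p = 2.78e-05). The cell cycle inhibitors CDKN1C and CDKN1A rose from 0.452 ± 0.0361 kb to 2.7 ± 0.0983 kb (log2 1.75, adjusted p = 5.73e-05) and from 3.69 ± 0.219 kb to 5.95 ± 0.206 kb (log2 0.62, adjusted p = 0.000457). Among the largest falls, SIX3, a forebrain factor, went from 3.21 ± 0.107 kb to 0.165 ± 0.233 kb (log2 -2.53, adjusted p = 0.000317), GBX2, a hindbrain factor, went from 5.68 ± 0.231 kb to 0.814 ± 0.108 kb (log2 -2.24, adjusted p = 8.38e-06), and TLX3, a neuronal factor, went from 1.81 ± 0.25 kb to no listed base (adjusted p = 0.000156). PAX3, a muscle progenitor factor, fell from 1.66 ± 0.087 kb to 1.18 ± 0.00495 kb (log2 -0.36, adjusted p = 0.00209), and ID1, an inhibitor of myogenic factors, fell from 4.16 ± 0.0849 kb to 3.05 ± 0.0523 kb (log2 -0.39, adjusted p = 0.00404).

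Against the other genes, camera, the set test of limma, called 8 of the 26 lists for H3K4me3. The contractile list was higher (adjusted p = 1.03e-17, and adjusted p = 0.0701 with an estimated correlation). So was the coupling list (adjusted p = 3.86e-06, and adjusted p = 0.144 with an estimated correlation), and the glycolysis and glycogen genes, where 19 of 28 rose (adjusted p = 0.00629, and adjusted p = 0.144 with an estimated correlation). Cell cycle genes were lower than the rest, with 6 of 38 higher and 10 lower (adjusted p = 1.84e-05, and adjusted p = 0.0701 with an estimated correlation), and a median of -0.07 that was -0.28 with quantile scaling. Developmental transcription factors outside the HOX clusters were lower, with 14 of 52 higher and 19 lower (adjusted p = 1.16e-05, and adjusted p = 0.144 with an estimated correlation), and their median of 0.09 turned to -0.21 with quantile scaling. HOX genes, which set position along the body axis, had 7 of 34 higher and 7 lower (adjusted p = 0.0409, and adjusted p = 0.277 with an estimated correlation), with a median of 0.07 that turned to -0.11 with quantile scaling. Interferon-stimulated genes had 4 of 27 higher and 5 lower (adjusted p = 0.000313, and adjusted p = 0.277 with an estimated correlation), and cytoplasmic ribosomal protein genes 6 of 54 higher and 4 lower (adjusted p = 4.27e-05, and adjusted p = 0.277 with an estimated correlation). With quantile scaling the numbers higher and lower were 35 and 0 contractile, 19 and 2 coupling, 11 and 1 glycolysis, 4 and 25 cell cycle, 7 and 24 developmental, 5 and 13 HOX, 3 and 15 interferon and 1 and 27 ribosomal genes. Counts adjusted over the list alone were 36 contractile, 21 coupling and 21 glycolysis genes higher, and 9 cell cycle, 21 developmental, 7 HOX, 5 interferon and 3 ribosomal genes lower. The HOX call was also lost with quantile scaling (adjusted p = 0.72), with lists of equal length (adjusted p = 0.158), and without WT 0 h replicate 1 (adjusted p = 0.178) or WT 60 h replicate 2 (adjusted p = 0.0596).

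In H3K27ac, 24 of 33 contractile genes rose and 0 fell (median log2 1.65), 14 of 22 myogenic regulatory factors and partners rose and 0 fell, and 21 of 23 HOX genes rose and 0 fell. These counts were 27, 14 and 22 when adjusted over the list alone. With quantile scaling 16, 11 and 9 rose and 4, 3 and 0 fell. Most measured genes were higher, with a median of 0.77 outside the contractile list, and camera called 0 of the 24 lists with at least 5 measured genes against the rest (7 at an unadjusted p under 0.05), with 1 called without WT 60 h replicate 1 and 1 without WT 60 h replicate 2. DMPK, the myotonic dystrophy kinase, had no base at 0 h and 5.27 ± 0.0863 kb at 60 h (adjusted p = 6.82e-05). ENO3, the muscle enolase, rose from 0.139 ± 0.196 kb to 5.47 ± 0.094 kb (log2 3.26, adjusted p = 0.000525). BGN, a matrix proteoglycan, BCL2L1, which protects cells from apoptosis, and IGFBP5, a binding protein of insulin-like growth factors, had no base at 0 h. At 60 h they had 4.32 ± 0.293 kb, 5.03 ± 0.817 kb and 1.22 ± 0.099 kb. The same was seen for MEF2C (1.61 ± 0.175 kb), TTN (1.38 ± 0.358 kb) and MYOD1 (0.966 ± 0.112 kb), with adjusted p values from 5.37e-05 for MEF2C to 0.000255 for TTN. No base was listed at 60 h for CRY2, a clock repressor, POLD3, a DNA polymerase subunit, ADM, which encodes adrenomedullin, and EZH2, the H3K27 methyltransferase. At 0 h these had 3.52 ± 0.352 kb, 3.18 ± 0.188 kb, 2.5 ± 0.421 kb and 0.306 ± 0.0205 kb, and the adjusted p values were 0.00117, 5.37e-05, 0.00697 and 6.44e-05.

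In H3K27me3, LMO1, a transcription cofactor, had no base at 0 h and 4.44 ± 1.0 kb at 60 h (adjusted p = 0.00452). LIN28A, an RNA-binding protein of early embryos, went from 3.07 ± 1.19 kb to no listed base (adjusted p = 0.00735), and OLIG2, a glial factor, fell from 8.75 ± 3.23 kb to 1.01 ± 0.368 kb (log2 -2.59, adjusted p = 0.0109). Camera placed 4 of 16 lists below the other genes, whose median was 0.47. They were developmental transcription factors, with 7 of 88 higher and 4 lower (adjusted p = 0.000492, and adjusted p = 0.937 with an estimated correlation), HOX genes, with 1 of 23 higher and 0 lower (adjusted p = 0.0158, and adjusted p = 0.937 with an estimated correlation), neuronal genes, with 2 of 13 higher and 0 lower (adjusted p = 0.0349, and adjusted p = 0.937 with an estimated correlation), and satellite cell and progenitor genes, with 0 of 9 higher and 1 lower (adjusted p = 0.0349, and adjusted p = 0.841 with an estimated correlation). Adjusted over the list alone, 6 higher and 4 lower, 0 and 0, 2 and 0, and 0 and 1 were called. The test put the lists down although the mean changes of all but the last (0.17, 0.08, 0.11 and -0.08) were above 0. Quantile scaling ended these 4 calls (adjusted p = 0.303, 0.195, 0.437 and 0.195). Without WT 0 h replicate 2 the developmental and HOX lists turned to the other side (adjusted p = 0.817 each) and the neuronal list had 0.297. Without WT 60 h replicate 2 the neuronal list had 0.291 and the satellite list 0.0815, and the satellite list had 0.102 without WT 0 h replicate 1 and 0.0927 without WT 60 h replicate 1. At a -log10 q of at least 5, LMO1, LIN28A and OLIG2 had no listed base in either group, and with lists of equal length LMO1 was not called (adjusted p = 0.169).

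Over all genes tested by limma, 5349 of 12897 were higher and 723 lower in H3K4me3, 4590 of 8967 were higher and 666 lower in H3K27ac, and 648 of 3685 were higher and 24 lower in H3K27me3. With quantile scaling, which gives every library the same distribution, the splits were 2285 and 3377, 1615 and 1629, and 398 and 653, and with lists of equal length H3K27me3 had 132 and 155, so its split turned there too. The median log2 change of all genes moved from 0.17 to -0.06 for H3K4me3, from 0.77 to 0.00 for H3K27ac and from 0.47 to -0.19 for H3K27me3. Covered length was 27 ± 0.60 Mb at 60 h against 21.9 ± 0.188 Mb at 0 h for H3K4me3, and 19.1 ± 1.60 against 12.3 ± 0.975 Mb for H3K27ac. For H3K27me3 it was 5.96 ± 1.83 against 2.11 ± 1.42 Mb, a ratio of 2.82, or 5.38 without WT 0 h replicate 2, 0.837 with lists of equal length and 0.549 at a -log10 q of at least 5. None of the 3 pairs of groups overlapped, and each exact permutation test (two-sided) gave 0.333, the smallest p that 2 libraries against 2 allow. The background implied by the deposited p values was also higher at 60 h, with ratios of 2.60 for H3K4me3 and 2.02 for H3K27ac. The index of read depth had ratios of 2.40 and 1.16. Depth and a change of the marks with time were therefore not told apart in these totals. The share of H3K27ac peaks over 2.5 kb from every gene end was 62.3% ± 0.580 at 60 h and 71.8% ± 1.19 at 0 h. Gained regions, present in both 60 h libraries and in neither 0 h library, numbered 1668, 8698 and 3167 for H3K4me3, H3K27ac and H3K27me3, and lost ones 967, 5481 and 196. Splits that mixed the groups gave at most 43, 217 and 193. With lists of equal length H3K27ac had 3724 gained and 3605 lost, and H3K27me3 375 gained and 546 lost. Without WT 60 h replicate 1 the genes called numbered 3933 for H3K4me3, 2699 for H3K27ac and 219 for H3K27me3, where the full fit called 6072, 5256 and 672. Without WT 60 h replicate 2 H3K27ac had 3014, and without WT 0 h replicate 1 H3K27me3 had 224. Restricting lists to a -log10 q of at least 5 left 1 gene called for H3K27me3, and lists of equal length 3432 for H3K27ac and 287 for H3K27me3.

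The second comparison asked what the inhibitor did in proliferating cells (0 h). The peak lists of treated cells were shorter in H3K27ac and H3K4me3 and longer in H3K27me3, and list length was not shown to measure the level of a mark. H3K27ac covered 5.53 ± 1.08 Mb in CBP and 12.3 ± 0.975 Mb in WT, a ratio of 0.451, and H3K4me3 17.3 ± 0.0940 and 21.9 ± 0.188 Mb, a ratio of 0.789. H3K27me3 covered 29.9 ± 6.75 Mb in CBP and 2.11 ± 1.42 Mb in WT, a ratio of 14.1. PAX7, the defining factor of satellite cells (gene 100625823, Sscrofa11.1 chromosome 6, 77160827 to 77268626), fell in H3K27ac from 3.67 ± 0.397 kb to 0.699 ± 0.0113 kb (log2 -1.80, adjusted p = 0.000271).

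In H3K27ac, CDKN1A, a p53 target that stops the cell cycle, fell from 3.55 ± 0.746 kb to 0.402 ± 0.191 kb (log2 -2.17, adjusted p = 0.00608). KLF7, a zinc finger factor, fell from 3.89 ± 0.401 kb to 0.288 ± 0.408 kb (log2 -2.58, adjusted p = 0.00604). WFDC1, a secreted protease inhibitor, CHRNB1, a subunit of the muscle acetylcholine receptor, and EZH2 went to no listed base from 3.44 ± 0.523 kb, 2.42 ± 0.435 kb and 0.306 ± 0.0205 kb. Their adjusted p values were 0.000257, 0.00181 and 0.000271. The neighbouring genes MYF5 and MYF6, myogenic factors, fell from 5.42 ± 0.181 kb to 2.41 ± 0.91 kb (log2 -1.06, adjusted p = 0.0177) and from 3.9 ± 0.50 kb to 1.32 ± 0.626 kb (log2 -1.31, adjusted p = 0.0174). Both calls ended with quantile scaling (adjusted p = 0.0898 and 0.0735), without WT 0 h replicate 1 (adjusted p = 0.0861 and 0.0677) and without WT 0 h replicate 2 (adjusted p = 0.080 and 0.0837). EP300, which encodes the target p300, fell from 0.946 ± 0.0933 kb to 0.408 ± 0.0219 kb (log2 -0.67, adjusted p = 0.00488), but its change was 0.01 with quantile scaling (adjusted p = 0.954). With lists of equal length neither EP300 nor MYF5 was called (adjusted p = 0.203 and 0.0593). CCAR1, a cell cycle and apoptosis regulator, had no base in WT and 0.96 ± 0.0905 kb in CBP (adjusted p = 0.000509), and none in either group at a -log10 q of at least 5.

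By group, 8 of 16 satellite cell and progenitor genes fell in H3K27ac and 0 rose (median log2 -1.05). Of 21 cell cycle exit and p53 target genes, 12 fell and 1 rose (median -0.96), and of 30 extracellular matrix and fibroblast genes, 12 fell and 0 rose (median -0.74). Among 20 acetyltransferase, deacetylase and bromodomain genes 8 fell, and among 33 contractile genes 3 fell (median 0.00). The numbers that fell, adjusted over the list alone, were 9, 14, 12, 8 and 1. Camera called 0 of 24 lists against the other genes, whose median was -0.35, and 4 at an unadjusted p under 0.05. The smallest adjusted p values were 0.126 for the satellite list and 0.126 for the p53 list (0.965 with an estimated correlation for each). With quantile scaling the medians of the first 3 lists were -0.50, -0.45 and -0.11. Of the regions present in both WT libraries, 6947 were in neither CBP library, and 864 were gained, where splits that mixed the groups gave at most 292. Lost regions made up 54.2% of those near a gene end and 43.7% of those more distal (Fisher's exact test across regions, p = 6.43e-31). Distal peaks were 71.8% ± 1.19 of all in WT and 77.4% ± 1.01 in CBP.

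In H3K4me3, GFI1, a zinc finger repressor, PAX5, the B cell factor, and FGF19, a secreted growth factor, went to no listed base from 2.37 ± 0.0509 kb, 1.77 ± 0.00566 kb and 1.82 ± 0.132 kb. Their adjusted p values were 8.36e-05, 8.36e-05 and 8.87e-05. GDF6, a bone morphogenetic protein, fell from 2.7 ± 0.196 kb to 0.25 ± 0.354 kb (log2 -2.18, adjusted p = 0.00248). MYOD1 went from 0.996 ± 0.196 kb to no listed base (adjusted p = 0.000199), and its call ended with a -log10 q of at least 5 (adjusted p = 0.235) and with equal list lengths (adjusted p = 0.232). MYF5 fell from 4.39 ± 0.187 kb to 2.34 ± 0.0537 kb (log2 -0.78, adjusted p = 0.000199), and CDH15, the cadherin of satellite cells, fell from 2.16 ± 0.0594 kb to 1.05 ± 0.108 kb (log2 -0.78, adjusted p = 0.000478). DES, the muscle intermediate filament desmin, fell from 2.13 ± 0.205 kb to 0.529 ± 0.0686 kb (log2 -1.36, adjusted p = 0.000205), and TWIST2, a mesenchymal factor, fell from 3.74 ± 0.0926 kb to 1.79 ± 0.125 kb (log2 -0.89, adjusted p = 0.000218). TRIM14, an innate immune adaptor, had no base in WT and 0.776 ± 0.0559 kb in CBP (adjusted p = 0.000177). Of 52 developmental transcription factors outside the HOX clusters, 37 fell and 0 rose (median -0.60; adjusted p = 0.000763, and adjusted p = 0.348 with an estimated correlation). Of 35 extracellular matrix and fibroblast genes, 27 fell and 0 rose (median -0.49; adjusted p = 0.000311, and adjusted p = 0.348 with an estimated correlation), of 34 HOX genes 25 fell and 1 rose (adjusted p = 0.0113, and adjusted p = 0.348 with an estimated correlation), and of 32 WNT pathway genes 19 fell and 0 rose (adjusted p = 0.0274, and adjusted p = 0.348 with an estimated correlation). The WNT call was lost without WT 0 h replicate 1 (adjusted p = 0.105), and the WNT and HOX calls with lists of equal length (adjusted p = 0.214 and 0.292). Camera placed the contractile list above the other genes (adjusted p = 0.0113, and adjusted p = 0.391 with an estimated correlation), but 27 of its 39 genes had no listed base at 0 h in WT or CBP and could not fall. Among genes with a base at 0 h, a test added after the data were seen, 8 of the other 12 fell and 0 rose (median -0.38 against -0.19), and the list lay below the other genes without a call (adjusted p = 0.352). Adjusted over the list alone, 39, 28, 25, 20 and 6 genes of these 5 lists fell. With quantile scaling 29, 16, 12, 11 and 2 fell and 2, 0, 1, 0 and 6 rose.

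In H3K27me3, no base was listed in WT for TBX1, a developmental factor, MFNG, a Notch glycosyltransferase, CYP11A1, the first enzyme of steroid synthesis, and PDE2A, a phosphodiesterase. CBP cells had 13.6 ± 2.66 kb, 14.3 ± 2.48 kb, 13 ± 1.01 kb and 14.2 ± 2.18 kb (adjusted p = 0.000648, 0.000428, 0.000271 and 0.000328). The muscle genes MYMK (gene 100627299, Sscrofa11.1 chromosome 1, 273101674 to 273111721), PAX3 and RYR1, the calcium release channel, were higher too. MYMK went from 0.656 ± 0.928 kb to 7.66 ± 0.276 kb (log2 3.10, adjusted p = 0.00581). PAX3 and RYR1 had no base in WT and 2.08 ± 0.584 kb and 3.01 ± 0.481 kb in CBP (adjusted p = 0.00781 and 0.00386). With quantile scaling these 3 had changes of 0.78, 0.21 and 0.54 (adjusted p = 0.27, 0.678 and 0.297), while the first 4 kept their calls. Every measured HOX gene (23 of 23) and WNT pathway gene (22 of 22) rose, as did 70 of 88 developmental transcription factors, 10 of 13 contractile and 6 of 9 satellite cell genes. The same numbers rose adjusted over the list alone (23, 22, 70, 10 and 6). Their medians of 2.96, 2.42, 2.09, 2.01 and 1.47 became 0.69, 0.29, 0.11, 0.05 and -0.29 with quantile scaling. Camera called 0 of 16 lists against the other genes (1 at an unadjusted p under 0.05), with 1 called without WT 0 h replicate 1 and 3 without WT 0 h replicate 2.

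Over all genes tested, 126 of 8967 were higher and 2531 lower in H3K27ac (median log2 -0.35), 170 of 12897 higher and 5159 lower in H3K4me3 (median -0.18), and 2825 of 3685 higher and 0 lower in H3K27me3 (median 2.02). At an unadjusted p under 0.05 limma called 2876 H3K27me3 genes. With quantile scaling the splits were 758 and 1469, 1805 and 1699, and 286 and 495, and the medians 0.13, 0.05 and -0.10. The groups did not overlap in covered length for any mark (exact permutation p = 0.333 each, two-sided, the smallest possible). Regions gained in H3K27me3 numbered 9298 and lost ones 3 (at most 8 in mixed splits), and those lost in H3K4me3 1990 and gained 170 (at most 46). With lists of equal length 330 were gained and 76 lost in H3K27me3, 2272 gained and 2464 lost in H3K27ac, and 281 gained and 903 lost in H3K4me3. Few H3K27me3 peaks had a -log10 q of at least 5 in WT, 0 of 1338 and 28 of 2660 at 0 h and 23 of 8922 and 4 of 6174 at 60 h, against 2441 of 19317 and 1233 of 14723 in CBP at 0 h. CBP at 60 h also had few, 24 of 13258 and 18 of 12336. The H3K27me3 ratio of 14.1 was 27 without WT 0 h replicate 2 and 5.73 with lists of equal length, and without CBP 0 h replicate 1 there were 1855 calls. Without WT 0 h replicate 1 or CBP 0 h replicate 2, H3K27ac calls numbered 1618 and 1589 where the full fit had 2657. Lists of equal length gave 1353 H3K27ac and 671 H3K27me3 calls, and a -log10 q of at least 5 gave 1611 and 888.

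The third comparison asked what the inhibitor did in differentiating cells (60 h), which the series title ties to a block of differentiation. Contractile genes had less H3K4me3 in treated cells. Of 39 measured contractile and sarcomere genes, 28 fell and 0 rose, with a median log2 change of -0.73 against 0.04 in the other genes (adjusted p = 1.03e-29, and adjusted p = 0.0446 with an estimated correlation). MYL1 had 4.29 ± 0.235 kb in WT and MEF2C 3.9 ± 0.582 kb, and neither had a listed base in CBP (adjusted p = 4.41e-05 and 5.29e-05). Both had no base at 0 h either, so WT at 60 h alone gave them a spread, and these p values rest on the variance that limma shares between genes. H3K27ac covered 10.5 ± 1.74 Mb in CBP and 19.1 ± 1.60 Mb in WT, a ratio of 0.549.

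**Figure D2:**
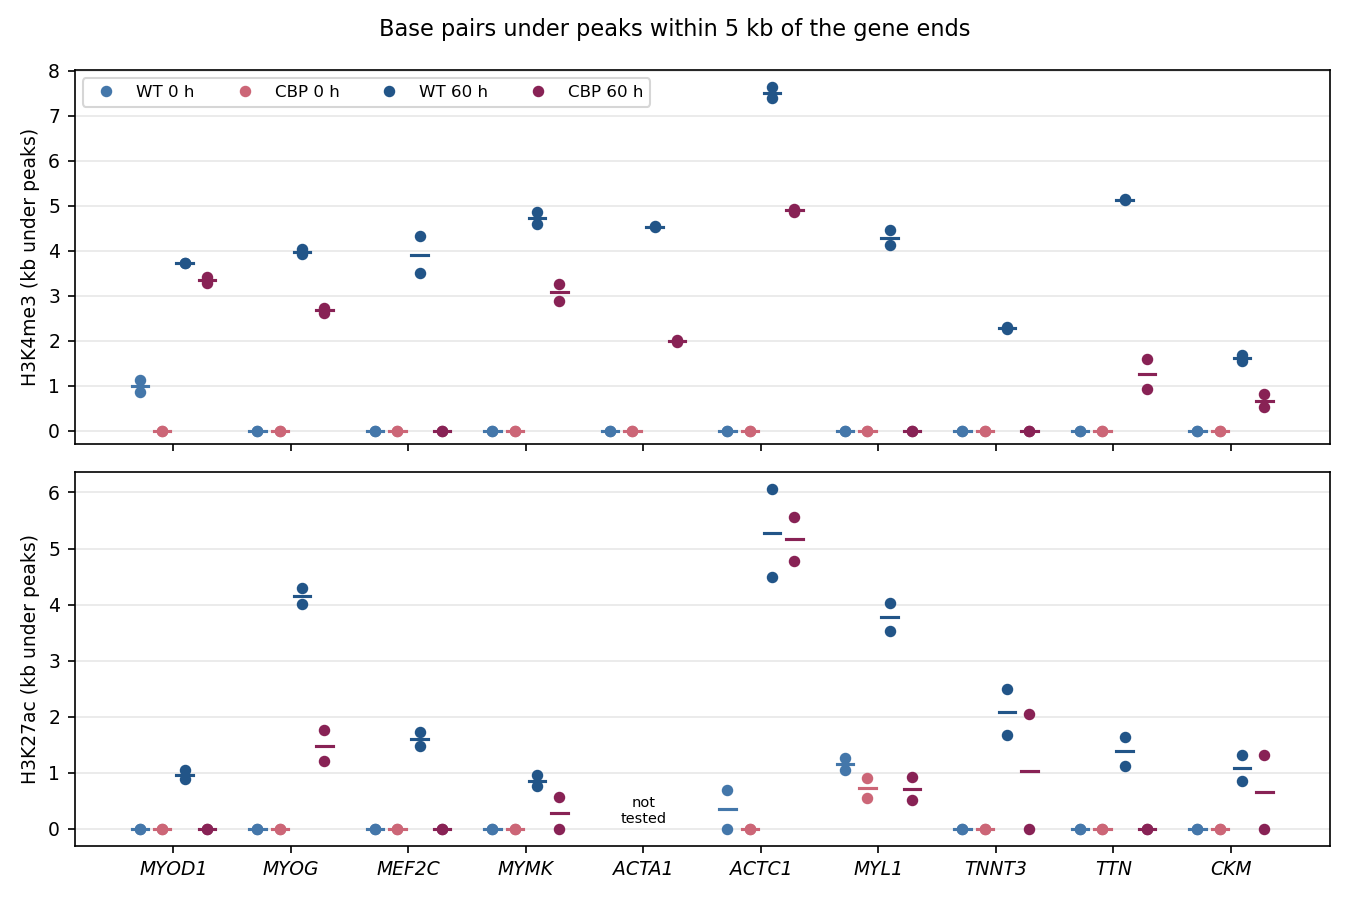
Kilobases under H3K4me3 (top) and H3K27ac (bottom) peaks within 5 kb of the gene ends for 10 muscle genes. Points are libraries, short lines are means of 2, and colours are the 4 conditions; too few libraries had H3K27ac at ACTA1 for a test. H3K4me3 at MYL1 and TNNT3 was listed in WT at 60 h alone, whereas ACTC1 kept 4.9 ± 0.0481 kb in CBP.

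In H3K4me3, XIRP2, an actin-binding muscle protein, and TNNT3, the fast troponin T, had 2.57 ± 0.00283 kb and 2.28 ± 0.024 kb in WT and no listed base in CBP (adjusted p = 4.82e-05 and 4.82e-05). EEF1A2, the elongation factor of mature muscle, had 5.04 ± 0.165 kb in WT and none in CBP (adjusted p = 3.92e-05). TTN fell from 5.13 ± 0.00566 kb to 1.26 ± 0.474 kb (log2 -1.71, adjusted p = 0.00188), ACTA1 fell from 4.53 ± 0.0233 kb to 1.99 ± 0.0304 kb (log2 -1.01, adjusted p = 0.000185), and ACTC1 fell from 7.51 ± 0.175 kb to 4.9 ± 0.0481 kb (log2 -0.57, adjusted p = 0.000666). Among the factors, MYOG (gene 497618, Sscrofa11.1 chromosome 9, 113783233 to 113785312) fell from 3.98 ± 0.0651 kb to 2.67 ± 0.0778 kb (log2 -0.50, adjusted p = 0.00261), MYMK fell from 4.73 ± 0.187 kb to 3.08 ± 0.27 kb (log2 -0.55, adjusted p = 0.00413), and MYF5 fell from 3.38 ± 0.0856 kb to 2.56 ± 0.0424 kb (log2 -0.34, adjusted p = 0.00465). MYF6 went from 0.872 ± 0.0361 kb to no listed base (adjusted p = 0.0032), and MYOD1 did not pass, with 3.73 ± 0.00424 kb in WT and 3.35 ± 0.0898 kb in CBP (adjusted p = 0.358). Higher in CBP were MSTN, the muscle growth inhibitor myostatin, from 1.86 ± 0.017 kb to 2.95 ± 0.075 kb (log2 0.55, adjusted p = 0.00201), and CMPK2, an interferon-stimulated kinase, with no base in WT and 1.65 ± 0.127 kb in CBP (adjusted p = 0.000535).

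Camera also placed 6 other lists below the rest in H3K4me3. Of 25 excitation-contraction coupling genes, 10 fell and 0 rose (adjusted p = 2.58e-07, and adjusted p = 0.18 with an estimated correlation). Of 22 myogenic regulatory factors and partners, 6 fell and 1 rose (adjusted p = 0.000221, and adjusted p = 0.127 with an estimated correlation). Glycolysis and glycogen genes, with 5 of 28 lower and 1 higher, had an adjusted p of 0.0343, and adjusted p = 0.27 with an estimated correlation. WNT pathway genes, with 9 of 32 lower and 2 higher, gave adjusted p = 0.0248, and adjusted p = 0.273 with an estimated correlation. Developmental transcription factors, with 9 of 52 lower and 4 higher, gave adjusted p = 0.0343, and adjusted p = 0.398 with an estimated correlation, and neuronal genes, with 3 of 9 lower and 0 higher, gave adjusted p = 0.0343, and adjusted p = 0.398 with an estimated correlation. Adjusted over the list alone, 29 contractile, 12 coupling, 6 myogenic, 6 glycolysis, 10 WNT, 11 developmental and 3 neuronal genes fell. Quantile scaling ended the glycolysis, WNT, developmental and neuronal calls (adjusted p = 0.0795, 0.0795, 0.142 and 0.0795), and lists of equal length the first 3 (adjusted p = 0.0869, 0.0925 and 0.23). Without WT 60 h replicate 2 the glycolysis, WNT, developmental and neuronal lists had adjusted p values of 0.179, 0.0982, 0.0994 and 0.0994. Without WT 60 h replicate 1 the neuronal list had 0.172. Without CBP 60 h replicate 1 the glycolysis and neuronal lists had 0.0591 and 0.0725, and without CBP 60 h replicate 2 the WNT and developmental lists had 0.109 and 0.109.

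In H3K27ac, BGN, PTMA, which encodes prothymosin alpha, and EP300 went to no listed base from 4.32 ± 0.293 kb, 4.05 ± 0.165 kb and 1.69 ± 0.0856 kb (adjusted p = 6.38e-05 each). MEF2C, IGFBP5, MYOD1 and TTN also had none in CBP, from 1.61 ± 0.175 kb, 1.22 ± 0.099 kb, 0.966 ± 0.112 kb and 1.38 ± 0.358 kb in WT. Their adjusted p values lay between 6.38e-05 for MEF2C and 0.00030 for TTN. ENO3 fell from 5.47 ± 0.094 kb to 0.138 ± 0.195 kb (log2 -3.26, adjusted p = 0.000623), CHRNB1 fell from 5.39 ± 0.191 kb to 0.152 ± 0.216 kb (log2 -3.22, adjusted p = 0.000345), MYF6 fell from 6.8 ± 1.0 kb to 0.941 ± 0.0834 kb (log2 -2.34, adjusted p = 0.00143), and MYL1 fell from 3.79 ± 0.352 kb to 0.715 ± 0.288 kb (log2 -1.84, adjusted p = 0.00211). MYOG fell from 4.15 ± 0.204 kb to 1.48 ± 0.392 kb (log2 -1.25, adjusted p = 0.00185) and PAX7 fell from 4.76 ± 0.342 kb to 2.84 ± 0.053 kb (log2 -0.65, adjusted p = 0.00328), but with quantile scaling their changes were -0.54 (adjusted p = 0.114) and -0.04 (adjusted p = 0.851). RET, a receptor tyrosine kinase, and PTGS1, a prostaglandin synthase, had no base in WT and 1.33 ± 0.0559 kb and 1.03 ± 0.000707 kb in CBP (adjusted p = 6.38e-05 each). By group, 14 of 21 glycolysis and glycogen genes fell and 0 rose (median -1.29), 13 of 20 coupling genes fell and 0 rose (median -1.10), 14 of 33 contractile genes fell and 1 rose (median -1.0), and 12 of 22 myogenic factors fell and 0 rose (median -0.61). Of 20 acetyltransferase, deacetylase and bromodomain genes 12 fell and 1 rose, and of 16 satellite cell genes 8 fell and 0 rose. Adjusted over the list alone, 15, 13, 14, 12, 12 and 8 fell. Camera called 0 of 24 lists against the other genes, whose median was -0.73 (0 lists at an unadjusted p under 0.05), and with quantile scaling the medians of the first 4 lists were -0.44, -0.27, -0.04 and 0.01.

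**Figure D3:**
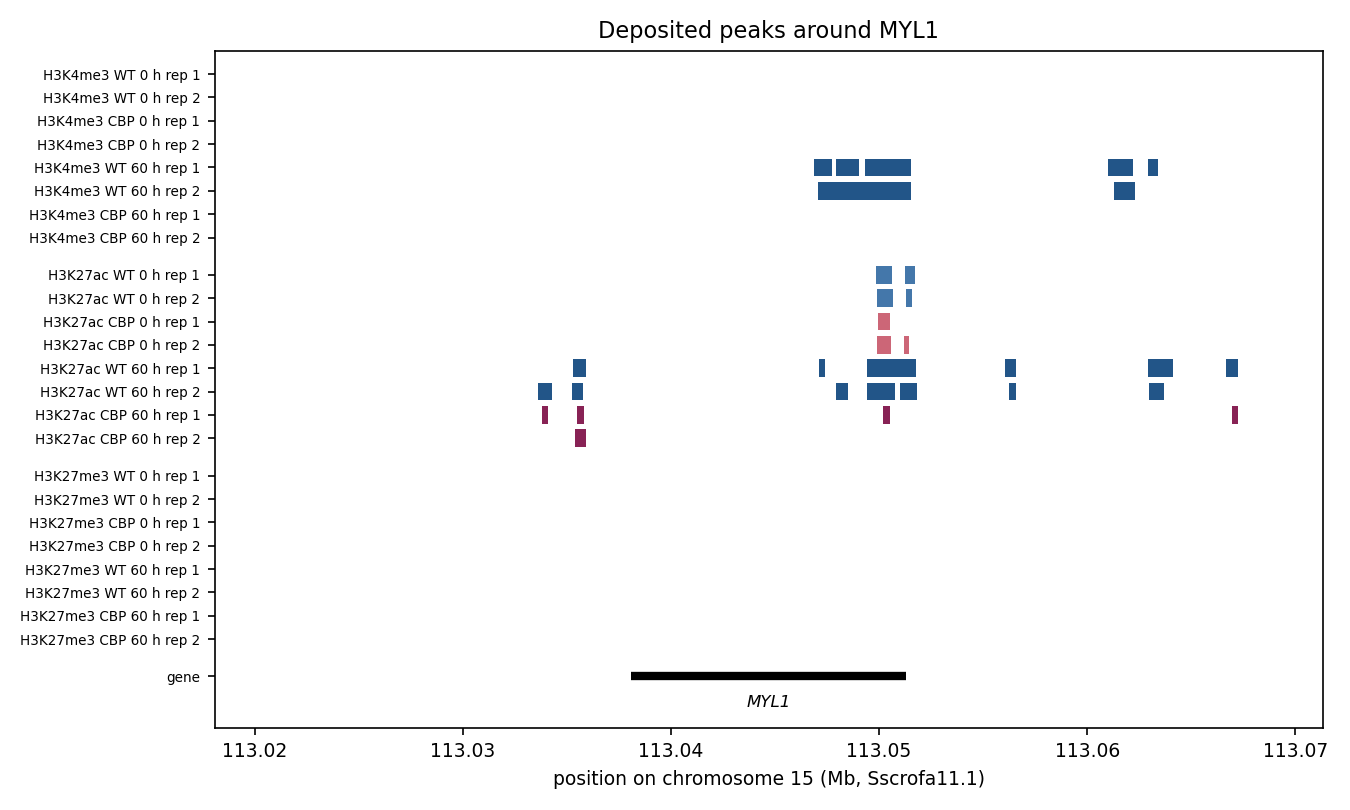
Deposited peaks of the 24 libraries around MYL1 on chromosome 15, with position in Mb (Sscrofa11.1) on the horizontal axis and a line per library. Boxes are peaks, coloured by condition, and the black bar is the gene. H3K4me3 peaks were listed in both WT libraries at 60 h and in no other library.

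In H3K27me3, KRT35, a hair keratin, had no base in WT and 5.28 ± 1.14 kb in CBP (adjusted p = 0.00597), and DMBX1, a brain homeobox factor, rose from 0.428 ± 0.169 kb to 6.61 ± 0.752 kb (log2 2.94, adjusted p = 0.00597). Without CBP 60 h replicate 1 their adjusted p values were 0.062 and 0.0683, and without CBP 60 h replicate 2 0.0548 and 0.0614. DMBX1 had no listed base in either group at a -log10 q of at least 5, and an adjusted p of 0.505 with lists of equal length. Covered length was 9.89 ± 0.667 Mb in CBP and 5.96 ± 1.83 Mb in WT, a ratio of 1.66 that turned to 0.971 with lists of equal length. Camera called 0 of 16 lists (4 at an unadjusted p under 0.05), with 1 called without WT 60 h replicate 2.

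Over all genes tested, 1275 of 12897 were higher and 835 lower in H3K4me3 (median log2 0.04), 238 of 8967 higher and 4229 lower in H3K27ac (median -0.73), and 413 of 3685 higher and 118 lower in H3K27me3 (median 0.16). With quantile scaling the splits were 1113 and 1102, 995 and 1141, and 471 and 344, and the medians 0.00, 0.03 and -0.10. The H3K27me3 split turned with lists of equal length (136 higher and 154 lower). Covered length of H3K4me3 was 27.6 ± 0.0832 Mb in CBP and 27 ± 0.60 Mb in WT. The groups did not overlap for any mark (exact permutation p = 0.333 each, two-sided). Lost and gained regions numbered 6939 and 1400 for H3K27ac (at most 495 in mixed splits), 832 and 929 for H3K4me3 (at most 67), and 1100 and 3847 for H3K27me3 (at most 469). With lists of equal length 2267 were lost in H3K27ac, and 368 were lost and 294 gained in H3K27me3. H3K27ac regions were lost in 39.0% of those near a gene end and 38.0% of distal ones (Fisher's exact test, p = 0.177). The H3K27me3 calls rested on both CBP libraries: without CBP 60 h replicate 1 or replicate 2 there were 0, without WT 60 h replicate 1 or 2 there were 351 and 230, and 2 at a -log10 q of at least 5. Without WT 60 h replicate 1 or 2, H3K27ac calls numbered 1786 and 2246, and with lists of equal length 2486, where the full fit had 4467. H3K4me3 calls, 2110 in the full fit, were 932 and 923 without those libraries and 1190 and 1241 without CBP 60 h replicate 1 or 2.

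The effects of the inhibitor at the 2 times were then compared. Among contractile genes in H3K4me3, 26 of 39 had a lower effect at 60 h than at 0 h and 5 a higher one (adjusted p = 1.07e-33, and adjusted p = 0.035 with an estimated correlation, and 26 and 5 over the list alone). Of these 39, 27 had no listed base at 0 h in either group, so their difference was the effect at 60 h again. Among the 12 with a base at 0 h, 1 had a lower effect at 60 h and 5 a higher one, and the list was not called (adjusted p = 0.581), so no difference between the times was shown for it. Of the 5175, 2949 and 2109 genes with a called difference in H3K4me3, H3K27ac and H3K27me3, 331, 1342 and 162 had no base at 0 h and 69, 262 and 352 none at 60 h. In H3K27ac, 1370 genes were lower with CBP at both times, where 1194 would be if the lists were independent. In H3K4me3, 381 genes were lower at both times (334 if independent), and 555 were called in opposite directions. In H3K27me3, 262 genes were higher at both times, fewer than the 317 of independent lists, and 80 were called in opposite directions. In H3K27ac 103 were. The opposite counts that independent lists would give were not computed, so no excess of opposite calls is shown. In H3K4me3, with 5159 genes lower at 0 h and 1275 higher at 60 h, independent lists would also hold many opposite calls. Across genes, which are not independent replicates, the log2 effects at 0 h and 60 h had a Pearson r of 0.06 for H3K4me3, 0.07 for H3K27ac and 0.01 for H3K27me3 (Spearman's rho 0.04, 0.03 and 0.01).

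Of the 4590 genes that rose in H3K27ac with time in WT, 3004 were lower with CBP at 60 h, where independent lists would share 2165. In H3K4me3 these numbers were 646 of 5349 and 346, and in H3K27me3 101 of 648 and 20.8. Both comparisons used the same 2 WT libraries at 60 h, and unchanged simulated groups shared 31.6, 2.45 and 2.05 genes on average over 20 simulations. The simulated groups had no effect of time or inhibitor, so few genes were called and a small overlap was fixed in advance. The covariance of the log2 changes was -0.291, -0.0738 and -0.255 against -0.0388, -0.00749 and -0.119 in the simulations, and Pearson's r -0.45, -0.42 and -0.36 against -0.40, -0.48 and -0.52. With 1 WT library at 60 h for each comparison, a test added after the data were seen over genes chosen without those libraries, the excess stayed. The shared genes in H3K27ac numbered 809 and 886 for the 2 ways to split, where independent lists would share 494 and 555, in H3K4me3 188 and 227 against 92.5 and 99.3, and in H3K27me3 28 and 27 against 5.95 and 3.89. Anything common to both WT libraries at 60 h was not separated by this. A gene with no listed base in WT at 60 h could neither rise with time nor fall with CBP. This puts the number expected of independent lists too low, also with split libraries. The excess alone therefore does not show that the inhibitor acted on the genes that rose with time.

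Genes lower with CBP in H3K4me3 were more often also lower in H3K27ac than chance gave: 1296 against 1036 at 0 h and 364 against 269 at 60 h (Fisher's exact test across genes, adjusted p = 4.35e-35 and 6.46e-16 over 36 tests). Higher with time in both marks were 2380 genes, against 1918 by chance (Fisher's exact test, adjusted p = 2.52e-90). A gene with no listed base in WT could not fall with CBP, and one with none in WT at 60 h could not rise with time. This can put the numbers expected by chance too low. Neighbouring genes can also share a window, so genes are not independent. The excess alone therefore does not show that the 2 marks changed together. No overlap with H3K27me3 passed (Fisher's exact test, smallest adjusted p = 0.202). Within 1 kb of a gene end, the share of H3K4me3 genes that also had H3K27ac was 28.6% in WT and 12.5% in CBP at 0 h, and 51.9% and 25.0% at 60 h. Genes with both H3K4me3 and H3K27me3 numbered 31 and 133 at 0 h, and 174 and 176 at 60 h. At a -log10 q of at least 5 these were 0, 16, 0 and 0. All genes with H3K27me3 numbered 390 in WT and 2071 in CBP at 0 h. The share of H3K27me3 genes that also had H3K4me3 was 7.95% in WT and 6.42% in CBP at 0 h, and 17.9% and 14.3% at 60 h. Of 1778 genes that lost H3K27ac at 0 h, 18 gained H3K27me3, and of 1534 that kept it, 10 did (Fisher's exact p = 0.342). At 60 h these were 5 of 2313 and 6 of 3817 (Fisher's exact p = 0.757). Loss and gain lay at the same gene end in 2 of the 18 genes at 0 h and 0 of the 5 at 60 h.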

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

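All tests of explanations in this part were chosen after the results were seen, while the test of the difference between the times was planned. Each result here stood out because the effect of the inhibitor differed between 60 h and 0 h. By the difference in limma, this held for 5175 genes in H3K4me3, 2949 in H3K27ac and 2109 in H3K27me3. These counts depended on the processing, with 3285 to 4339, 1048 to 3434 and 1217 to 1998 without 1 library, and 2890, 2513 and 718 with quantile scaling. Of these 331, 1342 and 162 had no listed base at 0 h in either group and 69, 262 and 352 none at 60 h, so their difference was the effect at the other time again. In the full fit 4737 had the higher effect at 60 h and 438 the lower in H3K4me3. The split was 971 and 1978 in H3K27ac, and 143 and 1966 in H3K27me3. With quantile scaling, which removes a shift common to all genes, the splits turned to 1392 and 1498, 1489 and 1024, and 419 and 299. Of the genes named for the 2 inhibitor comparisons, the difference was called in H3K4me3 for 9 of 10 named at 0 h and 14 of 15 named at 60 h. In H3K27ac it was 6 of 10 and 13 of 15, and in H3K27me3 7 of 7 and 0 of 2.

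Among gene lists, the difference in H3K4me3 was called by camera for contractile genes (adjusted p = 1.07e-33), excitation-contraction coupling genes (adjusted p = 5.66e-06), neuronal genes (adjusted p = 0.0155) and glycolysis and glycogen genes (adjusted p = 0.0382), all lower than the other genes, and for HOX genes (adjusted p = 0.00999), higher than the other genes. The neuronal and glycolysis lists had medians of 0.15 and 0.10, above 0, against 0.23 in the genes outside the neuronal list, so they lagged the rest and did not turn down. With an estimated correlation 1 list remained, the contractile one. But 27 of 39 contractile and 10 of 25 coupling genes had no base at 0 h in either group, so their difference restated the effect at 60 h. Among genes with a base at 0 h the contractile (adjusted p = 0.581), coupling (adjusted p = 0.482), neuronal (adjusted p = 0.164) and glycolysis calls (adjusted p = 0.0798) were lost and the HOX call stayed (adjusted p = 0.0262). The neuronal call was also lost with quantile scaling (adjusted p = 0.474), lists of equal length (adjusted p = 0.0883), the whole gene span (adjusted p = 0.0779), a single gene end (adjusted p = 0.142), and without CBP 0 h replicate 1 (0.113), WT 60 h replicate 1 (0.284) or WT 60 h replicate 2 (0.23). The glycolysis call was lost with quantile scaling (adjusted p = 0.103), lists of equal length (adjusted p = 0.0883), a single gene end (adjusted p = 0.0557), and without WT 0 h replicate 1 (0.0756), CBP 0 h replicate 1 (0.113) or WT 60 h replicate 2 (0.142). The HOX call was lost with lists of equal length (adjusted p = 0.368). Fixed panel genes whose H3K4me3 effect was lower at 60 h than at 0 h, with the log2 difference, were MYOG (-0.50), MEF2C (-3.13), MYMK (-0.55), CKM (-0.88), ACTA1 (-1.01), ACTC1 (-0.57), MYL1 (-3.26), TNNT3 (-2.48), TTN (-1.71), RYR1 (-0.40) and IGF2 (-0.65). Those with the higher effect at 60 h were MYOD1 (1.44), MYF5 (0.44), PAX3 (0.34), CDH15 (0.91), DES (0.97), EP300 (0.34), EZH2 (0.53), CCND1 (0.44), ID3 (0.90), IGFBP5 (0.48), MSTN (0.29), HOXA9 (0.34) and HOXA13 (1.16). In H3K27ac the effect was lower at 60 h for MYOD1 (-1.55), MYOG (-1.25), MEF2C (-2.07), MYL1 (-1.40), TTN (-1.90), EP300 (-1.46) and IGFBP5 (-1.78), and higher for PAX7 (1.14), EZH2 (0.69) and HOXA9 (0.74). In H3K27me3 it was lower at 60 h for PAX3 (-2.54), MYMK (-2.74), RYR1 (-3.58) and HOXA13 (-3.62). With quantile scaling these last 4 calls were lost, at -0.55 for PAX3 (adjusted p = 0.467), -0.65 for MYMK (adjusted p = 0.544), -1.32 for RYR1 (adjusted p = 0.106) and -1.41 for HOXA13 (adjusted p = 0.158). Quantile scaling also ended the calls of MYF5, PAX3, EP300, EZH2, CCND1, IGF2, IGFBP5, MSTN, HOXA9 and HOXA13 in H3K4me3 and of MYOG and HOXA9 in H3K27ac. The 11 panel genes with the lower H3K4me3 effect had no base at 0 h in either group, nor did MYOD1, MYOG, MEF2C, TTN and IGFBP5 in H3K27ac, and EZH2 had no H3K27ac base at 60 h. Their differences are the effect at the other time alone, and where a group had no base they depend on the 500 bp added to each length.

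For peak number and covered length of H3K4me3, all libraries went 1 way at 0 h and the other way at 60 h. The ratios of CBP to WT in peak number were 0.879 at 0 h and 1.03 at 60 h, and those in covered length 0.789 and 1.02. The difference between these ratios was not tested. The peak ratio at 60 h was 0.996 with a -log10 q of at least 5.

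The turn in H3K4me3 covered length was weighed against the depth at which peaks were called. The background implied by the deposited p values had a ratio of CBP to WT of 0.634 at 0 h and 1.20 at 60 h, the values this explanation needs. These backgrounds were inferred from 7.38 to 30.7% of the peaks of a list, and calling depth may account for the turn in total length. This explanation needs a change above 0 in the contractile genes, whose median log2 change at 60 h was -0.729 (0.04 in the other genes). That goes against a shift shared by all genes. But the fall was known when the test was chosen, so it restates the pattern and is no separate test. Lower read depth of the CBP libraries was not weighed for these genes. The depth index of the H3K4me3 libraries had ratios of 0.853 at 0 h, so lower read depth stays open as a cause of the fall there, and 0.763 at 60 h, which argues against higher read depth behind the excess at 60 h alone, and an effect of the inhibitor on the total stays open as untested.

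The lower H3K27ac with the inhibitor was weighed against the same calling depth. At 60 h the implied background had a ratio of 1.28, where lower calling depth from the control libraries needs a value below 1. This argues against it only if the control libraries set that background, and the control used for calling is not given. The backgrounds at 60 h were inferred from 14.1 to 15.9% of the peaks of a list. The depth index of the H3K27ac libraries themselves had ratios of 0.847 at 60 h and 0.934 at 0 h, below 1 as a lower read depth needs, so lower read depth stays open as a cause at both times. Covered length fell much further (0.549 and 0.451), and how far such a drop in depth shortens a list was not measured. For H3K4me3, index ratios of 0.853 at 0 h and 0.763 at 60 h went with covered length ratios of 0.789 and 1.02. At 0 h the background ratio was 0.598 while H3K4me3 covered length fell less (0.789 against 0.451), so calling depth and loss of the mark cannot be told apart there. Lower enrichment of the CBP libraries as a whole and a loss of the mark cannot be told apart at 60 h, since 0 of 24 lists were called against the other genes and a loss over the whole genome would look alike. A loss of acetylation through CBP and p300, the targets of the inhibitor, stays open as untested.

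The H3K27me3 excess at 0 h was weighed against a longer list from the same sites and against weak enrichment in the WT libraries. With lists of equal length the ratio of covered length was 5.73, but this sets the strongest of many CBP peaks against all 1338 of a WT list, so a longer list from the same sites and a gain of the mark cannot be told apart. In the WT 0 h lists 0.70% of peaks had a -log10 q of at least 5, and weak enrichment there and a low level of the mark cannot be told apart without read depth. By library the share was 0 and 1.05%, against 0.258 and 0.0648% in WT at 60 h and 12.6 and 8.37% in CBP at 0 h. In CBP at 60 h it was 0.181 and 0.146%, so CBP at 0 h stood apart from all other groups. The WT libraries at 0 h lay on both sides of those at 60 h, so this share did not single out WT at 0 h. A gain of the mark with the inhibitor stays open as an untested hypothesis.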

How the results depend on the processing

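The tests with a window of the whole gene span or at a single gene end, and those over genes with a base at 0 h, were added after the data were seen, and all other settings were planned. Values in brackets name the comparison, time being 60 h against 0 h in WT and the difference that between the CBP effects at the 2 times. Named genes were chosen after the results were seen, with those that depended most on the processing left out, so how they held is no measure of robustness. Over all genes the rule takes for the largest changes and the panel, 3487 of 3914 alternatives kept direction and call, 406 lost the call and 21 turned. Only genes, and below only lists, called in the full fit were counted. Many genes were taken for the largest changes in these same data, so a high share kept is partly built in. For H3K27me3 with CBP at 60 h 167 of 250 kept direction and call, 81 lost the call and 2 turned. For gene lists 228 of 318 kept it, 87 lost it and 3 turned, the contractile list in H3K4me3 at 0 h, given below, and the HOX and developmental lists in H3K27me3 over time (adjusted p = 0.0158 and 0.000492 with all libraries, and from 1.35e-08 to 0.817 and from 3.61e-11 to 0.817 over the fits without 1 library). Counts of called genes stayed within 1.5 times in 141 of 189, list counts in 102 of 138, lost regions in 37 of 61 and gained regions in 36 of 61. Covered length moved by less than its spread in 54 of 63 (3 turned), peak number in 56 of 63 (3 turned), and distal share in 51 of 61 (1 turned). Leaving out 1 of 2 libraries, or the replicate block, moves these ratios by less than that spread nearly by construction. Most of these alternatives are of those kinds, so the 3 counts are no measure of robustness. Gene-end states stayed within 1.5 times in 5 of 16. Windows of 10 kb, no filter, placed chromosomes only and an added length of 100 bp moved none of these. Unless a sentence below gives it, the cause was not tested.

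With a -log10 q of at least 5, regions lost were H3K4me3 1322 (CBP at 0 h) and 463 (time), H3K27ac 3252 (time), H3K27me3 1 (CBP at 60 h). Regions gained were H3K4me3 607 (CBP at 60 h), H3K27ac 308 (CBP at 0 h), 572 (CBP at 60 h) and 5651 (time), H3K27me3 3 (CBP at 60 h). Peak number ratios were H3K4me3 0.905 (CBP at 0 h), 0.996 (CBP at 60 h) and 1.01 (time), H3K27ac 0.333 (CBP at 0 h) and 0.552 (CBP at 60 h), H3K27me3 131 (CBP at 0 h) and 0.964 (time). Covered length ratios were H3K27ac 0.298 (CBP at 0 h) and 0.447 (CBP at 60 h), H3K27me3 573 (CBP at 0 h) and 0.549 (time). Distal share ratios were H3K4me3 0.842 (CBP at 0 h), 1.03 (CBP at 60 h) and 1.05 (time), H3K27ac 0.779 (time), H3K27me3 1.06 (CBP at 60 h). Genes called were H3K27ac 1611 (CBP at 0 h), H3K27me3 888 (CBP at 0 h), 2 (CBP at 60 h), 1 (time) and 868 (the difference). Genes with H3K4me3 and H3K27me3 were 0, 16, 0 and 0 in WT and CBP at 0 h and WT and CBP at 60 h, and those with H3K4me3 and H3K27ac 1710, 411 and 1684 in WT and CBP at 0 h and in CBP at 60 h. A stricter filter removes peaks by its construction.

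With lists of equal length, regions lost were H3K4me3 903 (CBP at 0 h) and 485 (time), H3K27ac 2464 (CBP at 0 h), 2267 (CBP at 60 h) and 3605 (time), H3K27me3 76 (CBP at 0 h), 368 (CBP at 60 h) and 546 (time). Regions gained were H3K4me3 281 (CBP at 0 h), H3K27ac 2272 (CBP at 0 h) and 3724 (time), H3K27me3 330 (CBP at 0 h), 294 (CBP at 60 h) and 375 (time). Covered length ratios were H3K4me3 0.819 (CBP at 0 h), H3K27ac 0.673 (CBP at 0 h), H3K27me3 5.73 (CBP at 0 h), 0.971 (CBP at 60 h) and 0.837 (time). Genes called were H3K27ac 1353 (CBP at 0 h), 2486 (CBP at 60 h) and 3432 (time), H3K27me3 671 (CBP at 0 h), 290 (CBP at 60 h), 287 (time) and 681 (the difference). Lists called were H3K4me3 3 (CBP at 0 h), 4 (CBP at 60 h) and 2 (the difference), H3K27me3 2 (time). This setting shortens the longer lists by its construction.

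With quantile scaling, genes called were H3K4me3 3504 (CBP at 0 h) and 2890 (the difference), H3K27ac 2136 (CBP at 60 h) and 3244 (time), H3K27me3 781 (CBP at 0 h), 815 (CBP at 60 h), 1051 (time) and 718 (the difference). Lists called were H3K4me3 3 (CBP at 60 h) and 13 (time), H3K27ac 3 (time), H3K27me3 1 (CBP at 0 h), 1 (CBP at 60 h), 0 (time) and 2 (the difference). EP300 in H3K27ac at 0 h turned from -0.67 to 0.0135. Quantile scaling removes a shift common to all genes by its construction.

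With a window at a single gene end, genes called were H3K27me3 755 (CBP at 0 h), 114 (CBP at 60 h), 183 (time) and 625 (the difference). Lists called were H3K27ac 1 (time), H3K27me3 0 (time). With the whole gene span, lists called were H3K27ac 5 (time), H3K27me3 2 (time). With genes that had a base at 0 h, lists called were H3K4me3 1 (the difference). The contractile list in H3K4me3 at 0 h then turned from above the other genes to below them (adjusted p = 0.352, no call). Genes without a base at 0 h have no effect there by construction. With 2000 bp added, genes called were H3K27me3 328 (time). With an estimated correlation, lists called were H3K4me3 0 (CBP at 0 h), 1 (CBP at 60 h), 0 (time) and 1 (the difference), H3K27me3 0 (time). With a distal limit of 5 kb, distal share ratios were H3K4me3 1.02 (CBP at 60 h), H3K27ac 0.847 (time), H3K27me3 1.89 (CBP at 0 h), 1.18 (CBP at 60 h) and 1.56 (time). With 50% overlap, regions gained were H3K4me3 2687 (time). Within 2.5 kb of a gene end, genes with H3K4me3 and H3K27me3 were 62, 241, 314 and 304 in WT and CBP at 0 h and WT and CBP at 60 h, a wider window by construction.

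Leaving out 1 library, where the lone library of a group was assumed to vary like the other groups, gave the following ranges. Regions lost were H3K4me3 2267 to 3206 (CBP at 0 h), 997 to 1235 (CBP at 60 h) and 1117 to 1690 (time), H3K27ac 7297 to 10596 (CBP at 0 h), 7968 to 10654 (CBP at 60 h) and 5915 to 7820 (time), H3K27me3 4 to 11 (CBP at 0 h), 1456 to 3228 (CBP at 60 h) and 235 to 732 (time). Regions gained were H3K4me3 242 to 372 (CBP at 0 h), 1136 to 1870 (CBP at 60 h) and 1879 to 2335 (time), H3K27ac 1085 to 1795 (CBP at 0 h), 1691 to 4162 (CBP at 60 h) and 9224 to 12534 (time), H3K27me3 9317 to 17685 (CBP at 0 h), 4159 to 7823 (CBP at 60 h) and 3187 to 6965 (time). Peak number ratios were H3K4me3 0.865 to 0.893 (CBP at 0 h), 1.01 to 1.04 (CBP at 60 h) and 0.932 to 0.947 (time), H3K27ac 0.487 to 0.595 (CBP at 0 h), 0.609 to 0.754 (CBP at 60 h) and 1.16 to 1.3 (time), H3K27me3 6.4 to 12.7 (CBP at 0 h), 1.43 to 2.07 (CBP at 60 h) and 2.84 to 5.64 (time). Covered length ratios were H3K4me3 0.785 to 0.794 (CBP at 0 h), 1.01 to 1.04 (CBP at 60 h) and 1.21 to 1.25 (time), H3K27ac 0.388 to 0.513 (CBP at 0 h), 0.485 to 0.614 (CBP at 60 h) and 1.46 to 1.65 (time), H3K27me3 9.59 to 27 (CBP at 0 h), 1.36 to 2.12 (CBP at 60 h) and 1.91 to 5.38 (time). Distal share ratios were H3K4me3 0.795 to 0.812 (CBP at 0 h), 1.06 to 1.07 (CBP at 60 h) and 0.974 to 0.995 (time), H3K27ac 1.06 to 1.09 (CBP at 0 h), 1.07 to 1.1 (CBP at 60 h) and 0.858 to 0.878 (time), H3K27me3 1.56 to 1.6 (CBP at 0 h), 1.11 to 1.16 (CBP at 60 h) and 1.36 to 1.42 (time). Genes called were H3K4me3 3721 to 4078 (CBP at 0 h), 3933 to 4647 (time), 3285 to 4339 (the difference) and 923 to 1241 (CBP at 60 h), H3K27ac 1589 to 2189 (CBP at 0 h), 2699 to 4452 (time), 1048 to 3434 (the difference) and 1786 to 4809 (CBP at 60 h), H3K27me3 1855 to 2569 (CBP at 0 h), 219 to 639 (time), 1217 to 1998 (the difference) and 0 to 351 (CBP at 60 h). Lists called were H3K4me3 4 to 6 (CBP at 0 h), 3 to 6 (CBP at 60 h), 7 to 10 (time) and 3 to 6 (the difference), H3K27ac 0 to 0 (CBP at 0 h), 0 to 0 (CBP at 60 h), 0 to 1 (time) and 0 to 1 (the difference), H3K27me3 0 to 3 (CBP at 0 h), 0 to 1 (CBP at 60 h), 1 to 3 (time) and 0 to 4 (the difference). EP300 in H3K27ac at 0 h ranged from -0.74 to -0.60. Region counts rise here by construction, since 1 library then stands for its group.

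With the replicate number as a block, the genes called for CBP at 0 h, CBP at 60 h, time and the difference were 5002, 1875, 5765 and 4786 in H3K4me3, 2683, 4469, 5262 and 2838 in H3K27ac, and 2767, 390, 535 and 2010 in H3K27me3, and over time 1 list was called in H3K27ac (0 without the block) and 9 in H3K4me3 (8 without it). Deviations of libraries with the same number correlated at -0.0643 to 0.0734 between groups, except at 0.222 between WT and CBP at 0 h in H3K27me3. No pairing was used, and something shared by same-numbered libraries in that comparison was not excluded. Read depth is not given in the sources used here, so how far depth limits the shorter lists was not measured. Leaving a library out of the gene-end states was not run.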

Other observations

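The 1 test of an explanation in this part was chosen after the results were seen, while the gene lists were planned. With time in WT, H3K4me3 was higher at 13 of 19 Notch pathway genes and lower at 1, higher at 16 of 27 TGF-beta and BMP pathway genes and lower at 1, and higher at 10 of 18 myoblast fusion genes and lower at 1. Immediate early genes, which answer growth signals, had 19 of 27 higher with time and 0 lower, and with the inhibitor at 0 h 0 of 27 were higher and 20 lower. With the inhibitor at 0 h H3K4me3 was lower at 16 of 27 interferon-stimulated genes (1 higher), and at 60 h 6 were higher and 2 lower. H3K27ac at 0 h was lower at 7 of 10 adipocyte genes and 8 of 18 inflammatory genes, with 0 and 0 higher. With quantile scaling the numbers higher and lower were 11 and 4 Notch, 12 and 3 TGF-beta and BMP, 7 and 2 fusion, and 11 and 4 immediate early genes with time. With the inhibitor at 0 h they were 4 and 7 immediate early, 2 and 5 interferon-stimulated, 0 and 4 adipocyte and 2 and 7 inflammatory genes, and at 60 h 5 and 2 interferon-stimulated genes. Against the other genes none of these lists passed camera (adjusted p = 0.204, 0.141, 0.0701, 0.0701, 0.0889, 0.332, 0.389, 0.288 and 0.492, in this order). Numbers called after adjustment within each list were 13, 16, 11, 19, 20, 16, 6, 7 and 8.

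In H3K27ac, insulin and mTOR pathway genes had 15 of 21 higher with time and 11 lower with the inhibitor at 60 h. These numbers were 13 and 11 of 27 for mitochondrial genes, 11 and 14 of 29 for cell cycle genes, and 26 and 23 of 53 for ribosomal protein genes. Over all genes tested, 4590 of 8967 were higher with time and 4229 lower with the inhibitor. Against the other genes camera called none of these lists (adjusted p = 0.223, 0.668, 0.138 and 0.904 with time, and 0.954 for each with the inhibitor). With quantile scaling 8, 5, 4 and 4 were higher with time and 5, 3, 5 and 3 lower with the inhibitor. Both comparisons used the same WT libraries at 60 h. Histone methylation genes fell in H3K27ac at 9 of 27 at 0 h and 16 of 27 at 60 h, with 0 and 0 higher (camera, adjusted p = 0.492 and 0.575). With quantile scaling 7 and 5 fell. In H3K27me3 at 0 h the values were higher in CBP than in WT for 7 of 7 histone methylation genes, 6 of 7 Notch genes, 10 of 12 endothelial genes and 4 of 6 leukocyte genes, and lower for 0, as over all genes tested, where 2825 of 3685 were higher, and camera called none of these lists (adjusted p = 0.448, 0.491, 0.63 and 0.839). With quantile scaling the medians of these 4 were 0.51, 0.60, -0.40 and 0.21. After adjustment within each list, 7, 6, 10 and 4 rose.

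Replacement of H3K27ac by H3K27me3 at the gene end was tested for the genes that lost H3K27ac at 0 h. Of these, 1.01% gained H3K27me3, below the 5% set as the lower bound, which argues against replacement as the usual course of the loss. Loss and gain were counted over either end of a gene, and 2 of the 18 genes with both had them at the same end.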
